A study of Homo sapiens and Rattus norvegicus with 6 samples.

How the data were processed

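RNA sequencing was done on 6 libraries of 2 established cell lines, hFOB1.19 (human fetal osteoblast) and ROS1728 (rat, given in the labels as osteoblast). Each was left untreated, given exosome-free supernatant or given exosomes of umbilical cord mesenchymal stromal cells at 100 ng/ml for 48 h. Per the labels' protocols, total RNA was extracted with Trizol, RNA of high integrity was taken forward, and libraries were sequenced on an Ion Proton instrument. The deposited values are raw read counts per gene symbol, 1 table per species with 3 columns. Genome builds GRCh38 and Rnor 6.0 are named in the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads of overlapping genes and antisense partners cannot be told apart, and reads of near-identical copies may be split between symbols, so such genes are marked as uncertain.

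The tables list 41762 human and 37203 rat symbols. Total counts were 11091547, 11472612 and 9617480 for the untreated, supernatant and exosome libraries of hFOB1.19 and 2362439, 3014807 and 2587540 for those of ROS1728. The rat libraries are thus shallower, and a rat gene needs more CPM to reach the same precision. Genes with at least 20 reads summed over the 3 libraries of a line were kept, 16830 human and 11425 rat genes, holding at least 99.55% of the reads of each library. Library sizes were scaled within a line with TMM factors (0.9927, 1.001 and 1.006 in hFOB1.19, 1.035, 1.051 and 0.9197 in ROS1728), and log2 CPM used a prior count of 2. The share of reads in ribosomal RNA symbols was 0.565%, 0.531% and 0.483% in the human libraries and 1.74%, 2.42% and 3.19% in the rat ones.

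With 1 library per group no test between treatments exists within a line, and no p-value is given there. Genes were counted by a rule of size: a ratio of at least 2-fold whose 99% exact counting interval (Clopper-Pearson interval of the share of reads in 1 of 2 libraries, rescaled by library size) excludes 1. A gene was called outside both controls when the rule held against both in the same direction. The interval covers counting error only. It may be too narrow even for that, since PCR reads without molecular identifiers are not independent molecules. Yardsticks were the same count for each control library and counts drawn from a Poisson model of a common profile (100 sets). A fold against a library with 0 reads is given as a bound computed with 3 reads in that library. Setting such genes at their bound left every list median as it was.

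The 38 gene lists, the thresholds and the rule for named genes were fixed before the data were examined. The lists covered bone and matrix genes, signalling targets, the cell cycle, metabolism, stress responses, vesicle biology and markers of other cell types. A list with at least 5 measured members was described by its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. Named genes were the 12 highest and 12 lowest outside both controls per line with at least 50 reads, the 6 highest and 6 lowest for supernatant against untreated, genes outside both controls in both lines, genes past the threshold in the model of both lines, list members past the rule with up to 4 others per list, and the 5 most abundant genes. Unnamed loci, pseudogenes and sex-linked marker genes were left out of naming, and 3 genes that the rule names are not reported here. Positions of human genes are from GENCODE v29 on GRCh38, which matched 264 of 271 named human genes; no rat annotation was used here, so no rat positions are given.

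Genes of the 2 species were matched by symbol. Changes common to both lines were tested with edgeR 4.0.16 (quasi-likelihood, cell line plus treatment, filterByExpr, TMM, Benjamini-Hochberg, 2 residual degrees of freedom, 3 with pooled controls) on 10025 genes. Lists were tested on it with camera (preset correlation 0.01, and estimated) and fry from limma 3.58.1. DESeq2 1.42.0 and limma-voom were alternatives, as were other scalings, read minimums, fold thresholds, prior counts, thinned libraries and each library left out. Work was done in R 4.3.3, and figures in Python 3.11.15 with matplotlib 3.10.9.

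The rule of size and the edgeR model were tested on simulated counts with 200 changed genes. The rule of size was run on 16830 genes for the hFOB1.19 exosome library and 11425 for that of ROS1728. It recovered 93% and 89% of 3-fold and 100% and 100% of 6-fold changes, with 17 and 22 calls among unchanged genes. Its changed genes were drawn only from genes with at least 100 reads over the 3 libraries, so recovery below that was not tested. Of the 154 human and 1514 rat genes called in the real data, 70 and 1112 reach that minimum. For both lines, exosome against untreated on 10025 genes, edgeR recovered 87% and 100%, with 8 calls among unchanged genes. These simulations had a dispersion of 0.02, without the differences between lines that the real data hold.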

Results

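Gene expression was measured by RNA sequencing in a cell line of each of 2 species after exposure to exosomes, the small membrane vesicles that cells release. The vesicles came from mesenchymal stromal cells of human umbilical cord (uMSC). hFOB1.19 is a human fetal osteoblast line, and ROS1728 is given in the labels as a rat osteoblast line. Each line had 3 libraries, from untreated cells, from cells given exosome-free supernatant and from cells given exosomes at 100 ng/ml for 48 h. The origin and dose of the supernatant are not given in the sources used here. All cultures were in medium with 1% exosome-free serum for 48 h before RNA extraction. The 6 groups held 1 library each, so no difference within a line has a replicate check. Total read counts in hFOB1.19 were 11091547 (untreated), 11472612 (exosome-free supernatant) and 9617480 (exosome). In ROS1728 they were 2362439, 3014807 and 2587540 in the same order, and 3 reads there corresponded to 1.23, 0.951 and 1.27 CPM (counts scaled to library size). Intervals below cover counting error at most.

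The comparison within each line asked which genes differed in the exosome library from both control libraries, with each control library set against the other 2 as a yardstick. A gene counted as outside when its ratio of normalised counts was at least 2-fold against both and the 99% exact counting interval of each ratio excluded 1. In hFOB1.19, 67 of 16830 genes were higher and 87 were lower in the exosome library than in both controls, 0.915% of genes. The untreated library gave 102 higher and 157 lower genes by the same rule, and the supernatant library 111 and 27, totals of 259 and 138 genes beside the 154 of the exosome library. In ROS1728, 941 of 11425 genes were higher and 573 were lower in the exosome library, 13.3% of genes. The rat untreated library gave 23 higher and 41 lower genes and the supernatant library 11 and 21. Counting noise alone gave at most 8 genes for the human exosome library and 6 for the rat one in 100 simulated sets. With total read counts in place of TMM scaling, the rat split became 716 higher and 901 lower genes. That scaling moved the median gene of the rat exosome library by -0.156 log2 against untreated and by -0.193 against supernatant.

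**Figure D1:**
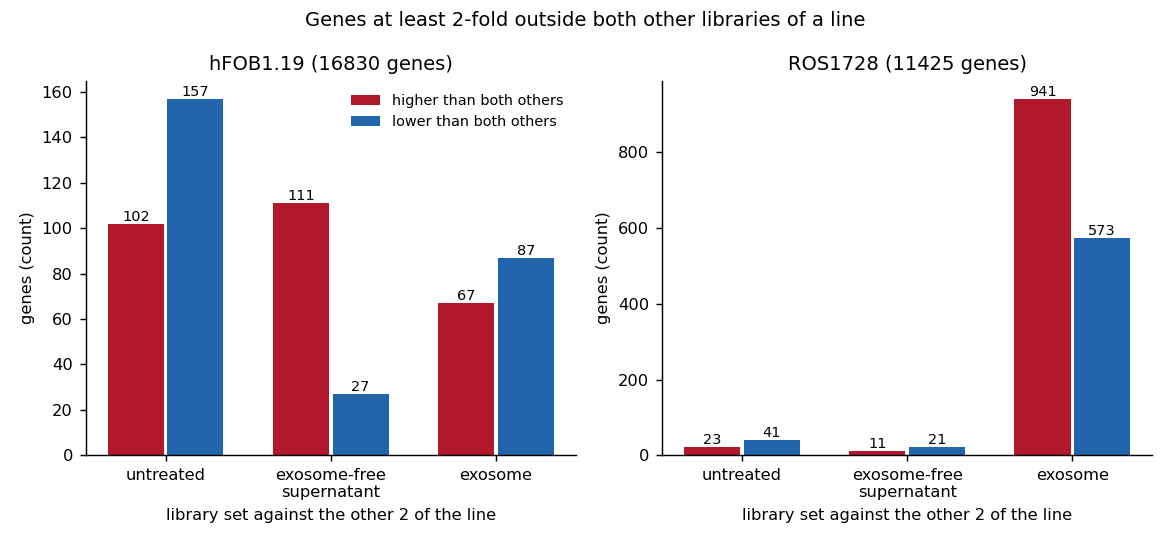
Bars give the number of genes (y axis, count) higher (red) or lower (blue) in 1 library than in both other libraries of its line, for each library on the x axis. The ROS1728 exosome library has 941 higher and 573 lower genes, against at most 41 in either direction for a rat control, while in hFOB1.19 the 3 libraries lie between 27 and 157.

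In hFOB1.19 the genes highest in the exosome library relative to both controls included AXIN2 and RNF43, the 2 of 15 measured Wnt targets that lay above both. The list's median for exosome against supernatant was 0.11, within the random range, with 1 member lower. AXIN2, a negative feedback target of beta-catenin (chromosome 17, 65528563 to 65561647, GRCh38), was at 14.6 CPM, against 1.82 in untreated and 3.31 in supernatant cells. Its ratio was 8.03-fold against untreated (99% interval 4.40 to 16.1) and 4.41-fold against supernatant (2.76 to 7.33). RNF43, a ubiquitin ligase that removes Wnt receptors, was 3.13-fold (1.31 to 8.49) and 3.01-fold (1.28 to 7.88) higher. RGCC, a regulator of the cell cycle, had 1, 9 and 55 reads in untreated, supernatant and exosome cells, and its ratio to supernatant was 7.26-fold (2.96 to 22.1). FLVCR2, a membrane transporter, was at 1.00, 3.23 and 8.90 CPM in the same order, and the hair keratin KRT81 at 0.728, 2.79 and 7.35 CPM. THBD, KRTAP1-5, CASC10, CTXN1 and EVA1C completed the leading genes, with ratios to supernatant between 2.39-fold for EVA1C and 4.12-fold for KRTAP1-5. BOLA2B and RPL21 also ranked among them, but both share sequence with near-identical copies, so their counts are uncertain.

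The genes lowest in the exosome library relative to both controls in hFOB1.19 included 3 that encode secreted signals, IL6, STC1 and CXCL12. IL6, an inflammatory cytokine that also promotes osteoclast formation (chromosome 7, 22725884 to 22732002, GRCh38), had 263, 126 and 22 reads in untreated, supernatant and exosome cells. It was 10.5-fold lower than in untreated (99% interval 6.03 to 20.01) and 4.82-fold lower than in supernatant cells (2.69 to 9.39). STC1, a secreted glycoprotein hormone, was at 39.8, 33.9 and 8.28 CPM, which is 4.80-fold and 4.10-fold lower in the exosome library. The chemokine CXCL12 was at 9.64, 7.59 and 2.07 CPM. PLEKHA6 was 6.74-fold (2.80 to 20.3) and 6.18-fold (2.56 to 18.7) lower. SERPINA3, LINC00460, TBX4, NFATC2, LINC00839, SIRPB1 and RNASE7 had at most 12 reads each in the exosome library and at least 17 in each control. SLC25A6 had 2065, 941 and 0 reads, but it lies in a region with an identical copy on another chromosome, so its count is uncertain.

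Gene lists fixed before the data were examined were described by the median log2 ratio of their members and its percentile among 10000 expression-matched random lists. In hFOB1.19, 7 of 35 lists lay below the central 95% of random lists against both controls and 0 lay above it. Control libraries stood apart in lists too, so standing apart does not by itself mark the exosome library. Collagen and matrix genes, for example, had a median of 0.37 for supernatant against untreated (percentile 100). For exosome against supernatant it was -0.25 (percentile 0). The inflammation list (NF-kB targets and cytokines, 22 genes) had medians of -0.38 against untreated and -0.61 against supernatant, with 3 and 4 members lower and 1 and 0 higher. IL1B was at 121, 28.4 and 10.6 CPM in untreated, supernatant and exosome cells, 2.69-fold (99% interval 2.01 to 3.65) below supernatant. The osteoclast regulation list, which did not stand apart with no read filter, had medians of -0.72 and -0.38 over 10 genes, and TNFRSF11B, the decoy receptor that restrains osteoclast formation, was at 9.004, 5.32 and 2.28 CPM. The growth factor and angiogenesis list had -0.38 and -0.39, and IGFBP5 was 5.09-fold and 2.11-fold lower. Glycolysis and hypoxia genes had -0.25 and -0.45 over 24 genes, with 2 and 4 members lower, NDRG1 among them at 135, 158 and 61.0 CPM. Matrix proteases had -0.47 and -0.17, immediate early genes -0.38 and -0.17, and YAP targets -0.24 and -0.21. For supernatant against untreated, osteoclast regulation (-0.47), matrix protease (-0.44) and immediate early genes (-0.20) also lay below the random range. Inflammation (0.16) and glycolysis and hypoxia genes (0.12) lay above it there, and the growth factor and YAP lists within it. Cell cycle genes gave no member past the rule in any pair, and MKI67 was at 864, 821 and 765 CPM.

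The exosome-free supernatant and exosome libraries of hFOB1.19 differed from the untreated library in many of the same genes. Supernatant cells had 527 higher and 221 lower genes than untreated cells, and exosome cells 370 and 344. Both were higher in 157 genes, where independent lists would share 11.6 and unchanged libraries set against a shared control 1.24, and both were lower in 102, against 4.52 and 0.68. In 1 gene they went opposite ways. The covariance of the log2 ratios across genes was 0.165, against 0.0382 in the simulation, and the correlation 0.585, against 0.487. Both comparisons share the untreated library, and the simulation held counting noise only. An untreated library that stood apart by itself would also give such an overlap, so these values cannot tell that from a shared response. The untreated library had the most genes outside the others in this line, 259 against 138 for supernatant and 154 for exosome.

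Interferon response genes were higher in both treated hFOB1.19 libraries than in the untreated one. Their median over 25 genes was 1.48 log2 above untreated in the supernatant library, with 19 members higher, and 1.04 in the exosome library, with 13 higher. MX1, an antiviral GTPase (chromosome 21, 41420304 to 41459214, GRCh38), was at 143.5 CPM in untreated, 621.8 in supernatant and 477 in exosome cells. IFI44L was at 5.82, 55.8 and 35.1 CPM, and the ubiquitin-like modifier ISG15 at 141.8, 468 and 313 CPM. Set directly against supernatant, the exosome library had a median of -0.42 for these genes, with 0 members past the 2-fold rule.

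Replication-dependent histone genes were higher than untreated in 7 of 7 measured members in the exosome library and in 4 in the supernatant library, with medians of 1.31 and 1.18. HIST1H2BK was at 40.3, 91.5 and 88.5 CPM in untreated, supernatant and exosome cells. Amino acid response genes lay lower in both, with medians of -0.76 in the exosome and -0.56 in the supernatant library and 6 and 4 of 18 members lower. Asparagine synthetase, ASNS, was at 213.5, 44.2 and 26.5 CPM, and the serine synthesis enzyme PSAT1 at 215.6, 74.4 and 53.01 CPM. Cholesterol synthesis genes had medians of 0.36 and 0.41 with 0 members past the rule.

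The osteoblast differentiation list of hFOB1.19 had a median of 0.38 above untreated in the exosome library and 0.43 in the supernatant library, and -0.09 for exosome against supernatant. BMP4, a bone-inducing growth factor, was 2.83-fold (99% interval 2.46 to 3.27) higher in exosome and 2.12-fold (1.83 to 2.45) higher in supernatant than in untreated cells. Alkaline phosphatase, ALPL, was at 7.28, 16.0 and 12.01 CPM, and COL1A1, the main collagen chain of bone, at 1256, 2118 and 2208 CPM. The collagen and matrix list was at 0.37 in supernatant against untreated and at 0.00 in exosome against untreated. The proteoglycan DCN was at 9.19, 36.1 and 28.4 CPM, while TNC was at 267, 88.2 and 80.3 CPM. Wnt targets had medians of 0.35 in the exosome and 0.60 in the supernatant library against untreated. Other genes that led the supernatant comparison were SOD3 (1, 94 and 52 reads in untreated, supernatant and exosome cells), SAA1 (31, 352 and 103 reads) and ABCA8 (74, 608 and 463 reads). ESM1 (173, 19 and 20 reads) and LAMA4 (266, 49 and 40 reads) were among the genes lower in supernatant than in untreated cells.

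**Figure D2:**
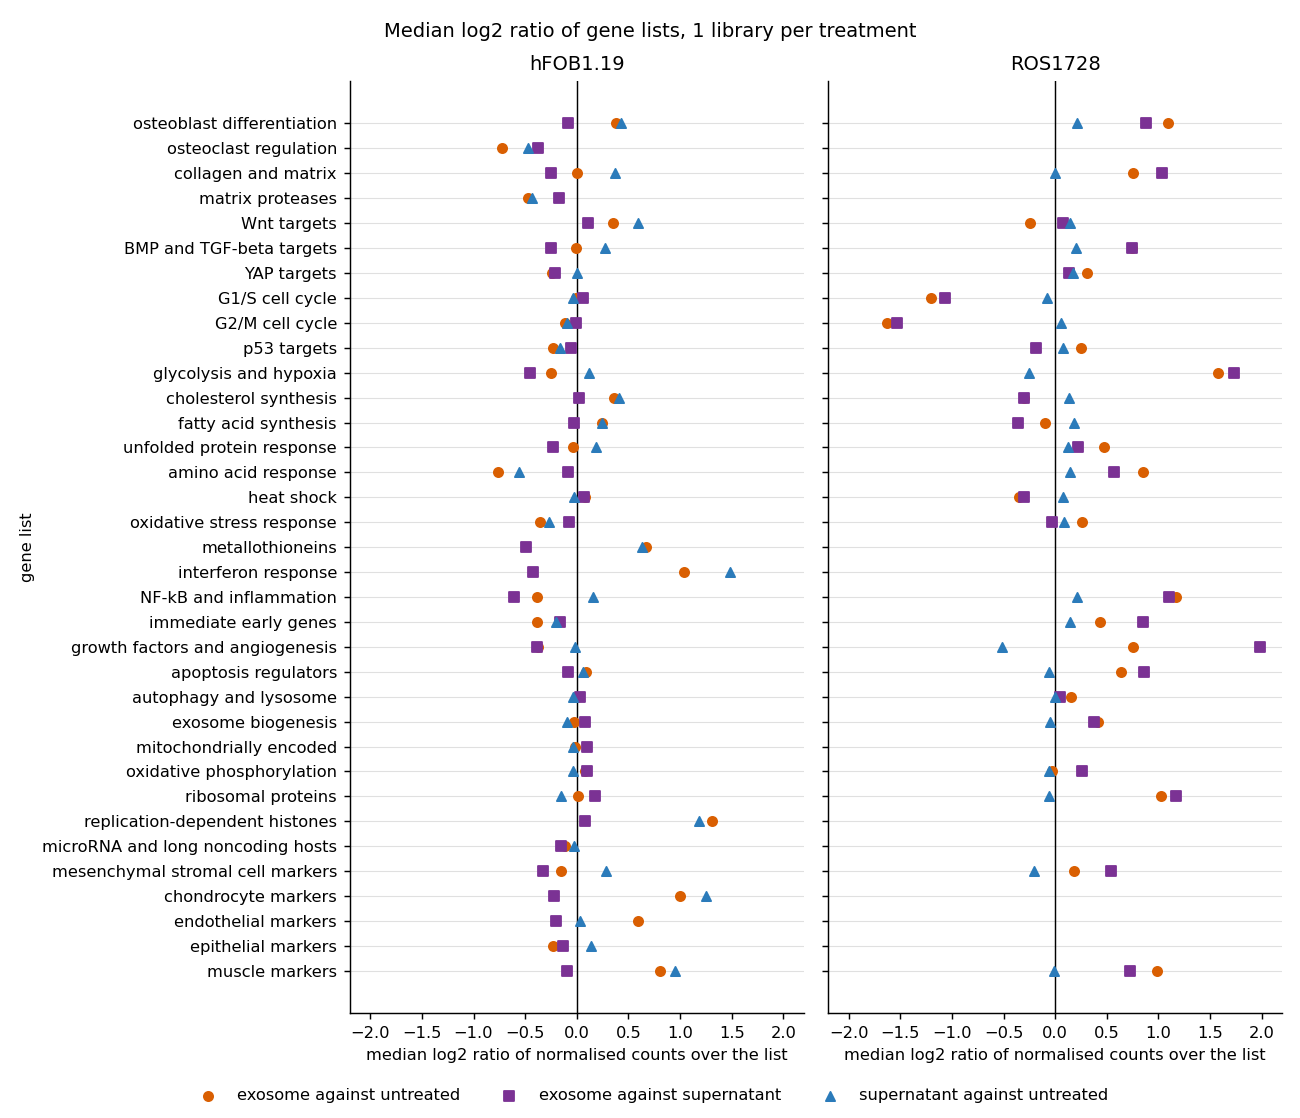
Each point is the median log2 ratio of normalised counts (x axis) over the measured members of a gene list (y axis), for exosome against untreated (circles), exosome against supernatant (squares) and supernatant against untreated (triangles), with 1 library per treatment. Lists with under 5 measured members in a line are not drawn. In hFOB1.19 the interferon list lies at 1.04 and 1.48 above untreated, and in ROS1728 glycolysis and hypoxia genes lie at 1.58 and 1.73 and G2/M genes at -1.63 and -1.53 in the exosome library against its controls.

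In ROS1728 the exosome library had higher levels of glycolysis and hypoxia genes than both controls and lower levels of cell cycle genes. Of 21 measured glycolysis and hypoxia genes, 17 were higher than both controls and 0 were lower, with medians of 1.58 log2 against untreated and 1.73 against supernatant. Vegfa, the main angiogenic factor, was at 92.8, 91.3 and 361 CPM in untreated, supernatant and exosome cells, 3.89-fold (99% interval 3.21 to 4.75) above untreated. The glycolytic enzyme gene Pgk1 was at 282, 253 and 845 CPM, the glucose transporter Slc2a1 at 250.5, 194 and 638 CPM, and Aldoc at 244, 127 and 807 CPM. Ndrg1, a hypoxia-responsive gene, was 8.17-fold (5.96 to 11.48) above untreated and 17.96-fold (12.1 to 28.0) above supernatant. Ankrd37 had 0, 1 and 21 reads, at least 7.20-fold above untreated.

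G2/M genes had medians of -1.63 and -1.53 in the rat exosome library, with 14 of 20 lower than both controls, and G1/S genes -1.20 and -1.07, with 11 of 22 lower. Topoisomerase Top2a was at 666, 693 and 215 CPM in untreated, supernatant and exosome cells. The mitotic kinase Aurka was at 151, 184 and 16.0 CPM, 9.39-fold (99% interval 6.11 to 15.2) and 11.46-fold (7.53 to 18.4) lower. Mcm5, a subunit of the replicative helicase, was at 463, 464 and 200 CPM and Rrm2, a subunit of ribonucleotide reductase, at 32.4, 22.2 and 5.49 CPM. Supernatant against untreated gave 0 members of either list past the rule.

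Ribosomal protein genes were higher than both rat controls in 15 of 31 measured members, with medians of 1.02 and 1.17. Rps3 was at 821, 819 and 3645 CPM and Rpl19 at 113, 121 and 504 CPM in untreated, supernatant and exosome cells. After a fit on transcript length and GC content their median against the mean of the controls was 0.66, against 0.98 before. The same library had more reads in ribosomal RNA symbols, 3.19% against 1.74% in untreated and 2.42% in supernatant cells, and more in its 10 largest genes, 8.42% against 5.50% and 5.90%. All 4 measured epithelial keratin genes were higher than both controls, among them Krt19 at 169, 184 and 1070 CPM and Krt18 at 186, 151 and 649 CPM. The mesenchymal filament gene Vim was at 7838, 6813 and 19030 CPM.

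Among single genes in ROS1728, the aldose reductase gene Akr1b1 was 16.6-fold (99% interval 12.8 to 22.0) above untreated and 18.99-fold (14.8 to 24.8) above supernatant, at 674 CPM in the exosome library. The somatostatin gene Sst was at 18.1, 18.4 and 205 CPM in untreated, supernatant and exosome cells and the calcium-binding protein gene Calb1 at 4.93, 2.22 and 57.0 CPM. Lamb3, Rragd, Eef1a2, Fbxl16, RT1-O1 and Rpl30 also led, with ratios to untreated between 6.96-fold for Rpl30 and 10.5-fold for Lamb3. The metallothionein genes Mt2A and Mt1m were 14.0-fold (9.20 to 22.3) and 5.96-fold (3.96 to 9.34) above untreated. In the other direction, the aldehyde dehydrogenase gene Aldh3a1 was at 1068, 1134 and 70.1 CPM, 15.2-fold (12.4 to 18.9) below untreated. Sgk1, a serum- and glucocorticoid-induced kinase, had 145, 165 and 7 reads, Cyp1b1 41, 69 and 2, and Fat4 56, 73 and 5. Adamts15, Ns5atp9, Sema4a, Mterf, Slc4a4, Ccp110 and Fabp3 had at most 9 reads each in the exosome library and at least 15 in each control.

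Some osteoblast and matrix genes were higher in the rat exosome library. Of 24 osteoblast differentiation genes, 4 reached 10 CPM in untreated cells and 8 passed the read filter, while Sp7, Bglap and Ibsp had 0 reads in all 3 libraries, as had 6 of 13 mitochondrially encoded genes. Their medians were 1.09 against untreated and 0.88 against supernatant, with 4 higher than both controls and 1 lower. Col1a1 had 5, 25 and 46 reads in untreated, supernatant and exosome cells, Dlx5 13, 23 and 38, Sparc 5, 8 and 21, and Pth1r, the parathyroid hormone receptor, 10, 15 and 40. Spp1, which encodes the bone matrix protein osteopontin, went the other way at 127, 138 and 24.1 CPM, 5.26-fold (99% interval 3.64 to 7.82) below untreated. The collagen and matrix list had medians of 0.75 and 1.03, with 8 of 17 higher than both controls and 1 lower. Among these genes the cross-linking enzyme Loxl2 was at 61.6, 61.8 and 242 CPM, the collagen prolyl hydroxylase P4ha1 at 54.2, 46.0 and 239 CPM, and the proteoglycan Vcan at 917, 917 and 342 CPM. Neither list stood apart from random lists when at least 100 reads per gene were required, and the median of the collagen and matrix list against supernatant turned to -0.153. With no read filter the osteoblast list did not stand apart either.

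Smaller groups also stood apart in the rat exosome library. BMP and TGF-beta targets had medians of 0.75 and 0.74, with 5 of 13 higher than both controls, among them Id1 at 27.5, 41.5 and 113 CPM. The inflammation list had medians of 1.17 and 1.10, with Nfkbia at 115, 86.2 and 283 CPM and Sod2 at 37.4, 28.9 and 126 CPM, but it did not stand apart from random lists with no read filter. Amino acid response genes had 0.85 and 0.57, with Asns 4.61-fold (99% interval 3.54 to 6.09) above untreated. The exosome biogenesis list had 0.42 and 0.38, and the tetraspanin genes Cd9 and Cd63, which encode exosome surface proteins, were at 5.75, 9.83 and 36.3 CPM and at 32.0, 34.6 and 75.1 CPM. Heat shock genes had medians of -0.35 and -0.30, within the random range, though Hspa1b at 259, 301 and 76.0 CPM and 3 others were lower than both controls and 1 was higher. The interferon list had 3 measured members in this line, with 0 past the rule.

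The exosome-free supernatant library of ROS1728 lay close to the untreated one, with 81 higher and 72 lower genes, where counting noise gave at most 39 in total. Of these genes, 41 were also higher and 23 also lower in exosome than in untreated cells, and 7 went opposite ways. Independent lists would share 8.98 and 5.41, but here too the untreated library was shared. Stc2 (1, 14 and 54 reads in untreated, supernatant and exosome cells) and Col1a1 were among the genes higher in supernatant, and Gabarapl2 (44, 15 and 11 reads) among those lower. Across genes, Pearson's r of log2 CPM was 0.978 between these libraries, against 0.905 and 0.909 for the exosome library with untreated and supernatant. In hFOB1.19 the 3 pairs had 0.976, 0.981 and 0.979. Genes are not independent replicates, so these values carry no p.

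**Figure D3:**
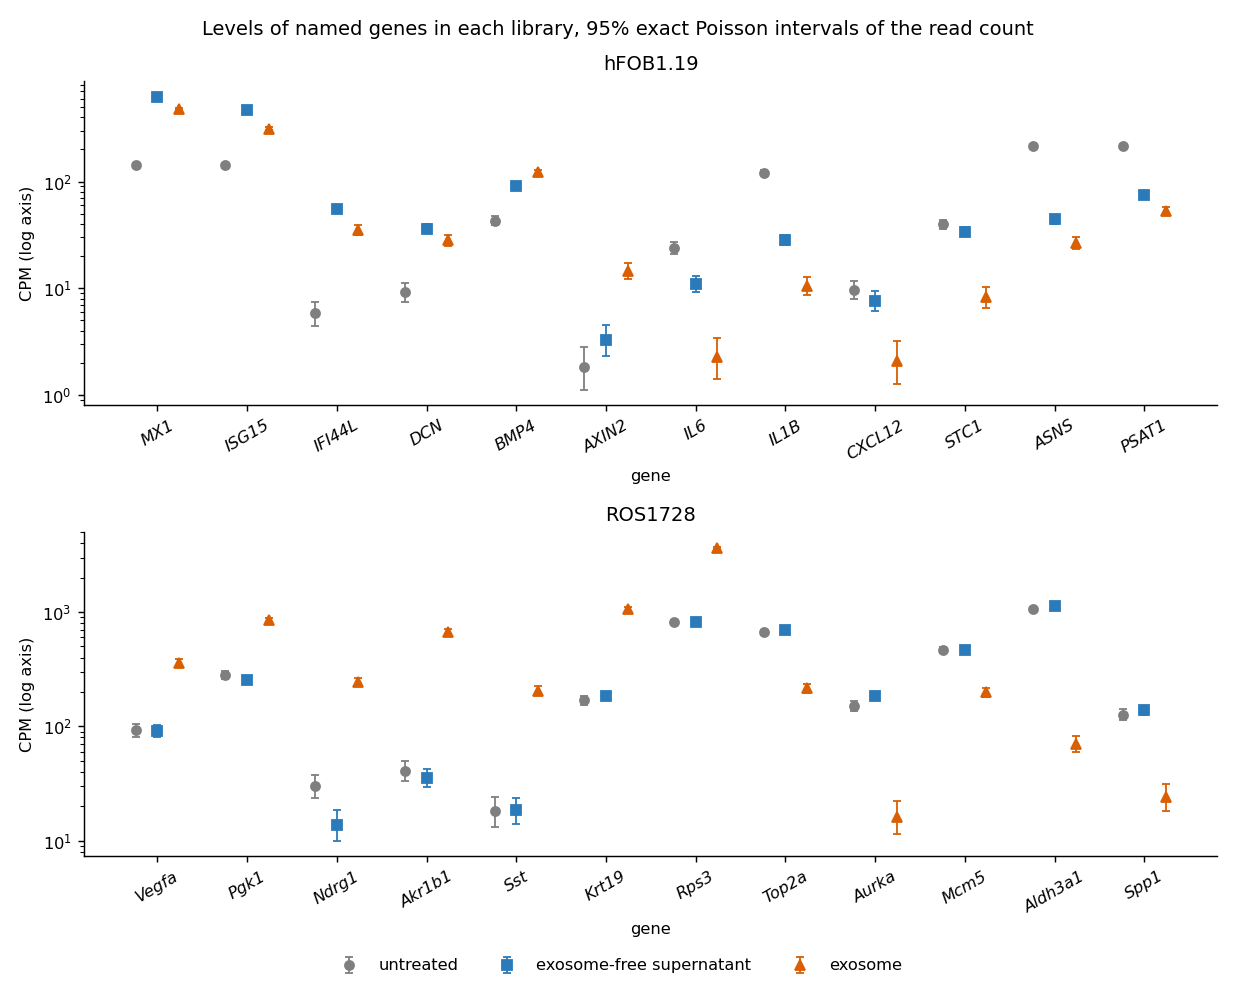
Points are the levels of 12 genes per line in CPM (y axis, log scale) in the untreated (grey circles), supernatant (blue squares) and exosome (orange triangles) library, with 95% exact Poisson intervals of the read count as bars. The genes were picked from those named in the text, so they do not stand for all genes. In ROS1728 the exosome library departs from both controls in each gene shown, as for Aldh3a1 at 70.1 against 1068 and 1134 CPM. Of all 11425 rat genes, 13.3% lay outside both controls. In hFOB1.19, MX1, DCN, ASNS and PSAT1 lie nearer each other in the supernatant and exosome libraries than to the untreated one.

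The next comparison asked whether the 2 lines differed alike. The 7925 genes matched by symbol held 8 of the 67 higher and 16 of the 87 lower genes of the hFOB1.19 exosome library. In ROS1728 they held 480 higher and 381 lower genes, so few human genes could overlap at all. Of the matched genes, 0 were higher and 1 was lower than both controls in the exosome libraries of both lines. Independent lists would share 0.485 and 0.769. The gene was UGT8, a ceramide galactosyltransferase, with 10, 10 and 0 reads in the human libraries, at least 2.93-fold and 2.81-fold lower, and 89, 63 and 19 reads in the rat ones. In 3 genes, NDRG1 and DPP4 among them, the exosome libraries lay outside both controls in opposite directions, where chance gives 1.35 genes. The log2 ratios of the exosome library to the mean of its controls had a Pearson's r of 0.0031 and a Spearman's rho of 0.0481 across genes between the lines. With the untreated library in its place the values were 0.0127 and 0.0181, and with the supernatant library -0.0107 and 0.0416.

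A model with cell line and treatment terms then tested changes common to both lines, with the 2 lines standing in for replicates. Its p-values set the mean change against the disagreement between the lines. All treatments share the same estimate of this spread. The test of supernatant against untreated is thus also set against the disagreement between the lines in their exosome libraries. With both controls pooled, the residual spread also holds the difference between the untreated and supernatant libraries. In edgeR's quasi-likelihood test, 0 of 10025 genes passed an adjusted p of 0.05 for exosome against untreated, where 298 had an unadjusted p under 0.05 and the smallest adjusted p was 0.954. For exosome against supernatant the counts were 0 and 199, for supernatant against untreated 0 and 60, and for exosome against both controls 0 and 678. DESeq2 gave 1, 0, 0 and 7 genes in that order and limma-voom 0, 0, 0 and 1. Adjusted over the list alone, 0 of 461 fixed list genes passed in edgeR for any of the 4 contrasts. With 1 exosome library left out, the contrasts with exosome rested on a lone exosome library that its own term fitted exactly. They then did not test a change common to both lines. Supernatant against untreated, which kept both lines, gave 63 genes in edgeR without the hFOB1.19 exosome library and 70 without the ROS1728 one. Exosome against untreated gave 6 and 3 genes without the hFOB1.19 and the ROS1728 supernatant library. Leaving out a supernatant or untreated library likewise left a lone library of that treatment in the contrasts that set it against 1 other treatment.

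Gene set tests on the same model passed their threshold in some lists only with a preset correlation between genes. Camera with a correlation of 0.01 called 10 of 30 lists for exosome against untreated, with G2/M genes lower (median log2 fold change -0.66) and interferon genes higher (1.00) among them. The model held 12 interferon genes, while 3 of 25 passed the read filter in ROS1728, with 0 past the rule. The interferon value thus rests mainly on hFOB1.19, where the list median was 1.04. With that correlation camera called 7 lists for exosome against supernatant, 6 for supernatant against untreated and 8 for exosome against both controls. The 8 included glycolysis genes (0.61), ribosomal protein genes (0.53) and G2/M genes (-0.57). These medians were not shared by the lines. Against untreated, glycolysis genes were at -0.25 in hFOB1.19 and 1.58 in ROS1728, so they went opposite ways. Ribosomal protein genes were at 0.01 and 1.02 and G2/M genes at -0.11 and -1.63 in the same order. The G2/M and interferon lists had adjusted p = 0.693 with an estimated correlation for exosome against untreated, and the glycolysis, ribosomal protein and G2/M lists adjusted p = 0.767 with an estimated correlation for exosome against both controls. With an estimated correlation 0 lists passed in any contrast, and the smallest adjusted p was 0.693, 0.793, 0.81 and 0.767 in camera. Fry called 0 lists as well, with smallest adjusted p of 0.759, 0.854, 0.993 and 0.602.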

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

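Of the tests in this part, those for counting noise, added RNA and identical copies were chosen only after the result was seen, and those for transcript length and GC content and for human RNA before it. NDRG1 and DPP4 drew attention because the exosome library lay outside both controls in opposite directions in the 2 lines. The log2 ratio nearer 0 was -1.141 in hFOB1.19 and 2.999 in ROS1728 for NDRG1, and -1.151 and 1.555 for DPP4. With 1 library per group the difference between lines was not tested.

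The ROS1728 exosome library lay apart from both controls in 1514 genes, where simulated counting noise gave at most 6. Depth with independent reads is thus not the whole cause, but the simulation held no duplicated reads. The rat untreated and supernatant libraries also exceeded it, with 64 and 32 genes against at most 7 and 5. A fit on transcript length and GC content, taken from the human genes of the same symbol, left medians of 1.682 for glycolysis and hypoxia genes, -1.506 for G2/M genes and 0.6644 for ribosomal protein genes, against 1.658, -1.593 and 0.9836 before, so this trend is not the whole cause for these 3 lists. It could not be judged for the whole set, since 58.4% of the 1514 genes had a length. Added RNA from another source would dilute rat genes by 1 factor, and with total read scaling the median gene was at -0.156 and -0.193, the direction of dilution, but 573 genes lay at least 2-fold below both controls with TMM and 901 with total reads, so dilution does not account for the lower genes, while added RNA stays open for the higher ones. A difference between cultures or preparations could give the same picture as the exosomes, and 1 library per group cannot separate them.

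The all-or-none counts of hFOB1.19 may come from reads shared between identical copies. Of 6 pseudoautosomal genes 3 had 0 reads in 1 library and at least 50 in another, against 0 of 16824 other genes. The explanation was found from these same counts, so they leave it open. BOLA2 and BOLA2B differed by 2.51-fold and 3.86-fold between libraries singly and by 1.18-fold when summed. SERF1A and SERF1B still differed by 5.75-fold when summed, at 1.18, 6.8 and 6.52 CPM in untreated, supernatant and exosome cells. Sharing between these 2 symbols alone does not account for that pair. Reads dropped or counted elsewhere stay open, since the counting tool is not given. No biological explanation was tested.

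Some genes nearly silent in both rat controls had reads in the ROS1728 exosome library, and human RNA carried over from the vesicles could place such reads there. Of the 50 such genes highest in hFOB1.19, 17 had any read, and the 3 largest, FBLN1 with 38 reads among them, held 67.5% of 120 reads. Draws from the hFOB1.19 profile are no fair yardstick for that share, since the set holds mitochondrial and ribosomal genes that the rat table hardly counts, such as MT-CO2 with 1, 0 and 0 reads. The profile of the donor cells is not known either, so human RNA and a response of the rat cells both stay open.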

How the results depend on the processing

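The alternatives were fixed before the data were examined, so none of the tests in this part were chosen only after the result was seen. No call outside both controls turned its direction under another scaling, filter, threshold or depth. Of the 154 human and 1514 rat genes, 152 and 1502 kept their call with DESeq2 size factors, 150 and 1289 with total read scaling, 151 and 1475 with no filter and 120 and 1405 with libraries thinned to the smallest. Requiring 100 reads kept 68 of the 70 human and 1084 of the 1112 rat genes still in the table. List calls were the same with DESeq2 size factors, total read scaling and other prior counts. With no filter the osteoclast list (hFOB1.19) and the osteoblast differentiation and inflammation lists (ROS1728) no longer stood apart, and the immediate early, histone, epithelial and muscle lists (ROS1728) did. With at least 100 reads the amino acid list (hFOB1.19) stood apart, and the osteoblast differentiation and collagen lists (ROS1728) did not. A fit of each line alone leaves no residual degrees of freedom and was not run.

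Where a value moved by over 1.5 times the cause was not tested, except that by construction a stricter filter holds fewer genes and a lower threshold or no interval gives more. Total read scaling gave 901 rat genes lower. At least 100 reads gave 17 higher and 53 lower genes in hFOB1.19, 414, 210 and 379 in its pairs (exosome against untreated, exosome against supernatant, supernatant against untreated), 49 for rat supernatant against untreated and 0 in both lines. The median of rat collagen and matrix genes for exosome against supernatant reversed to -0.153 there. A 1.5-fold threshold gave 170 higher and 193 lower human genes with pairs of 1536, 1066 and 1445, 1508 higher and 1120 lower rat genes with pairs of 3424, 3560 and 427, and 9 genes in both lines. Without the counting interval there were 177 higher and 336 lower human genes with pairs of 1474, 1177 and 1334, 908 lower rat genes, 687 for rat supernatant against untreated and 4 in both lines. Thinned libraries gave 0 in both lines.

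Camera with an estimated correlation and fry called 0 lists each. In the model of both lines edgeR called 0 genes in each contrast, with 298, 199, 60 and 678 at an unadjusted p under 0.05. DESeq2 called 1 for exosome against untreated, CAMK2N1 (adjusted p = 0.0191), and 7 for exosome against both controls. limma-voom called 1 there, ALDH3A1 (adjusted p = 0.0192), and CAMK2N1 was named after its values were seen. With each library left out in turn, edgeR gave 0 to 1823 genes for exosome against untreated, 0 to 1919 for exosome against supernatant, 0 to 70 for supernatant against untreated and 0 to 1712 for exosome against both controls. The ranges of the 3 contrasts with exosome peaked without the hFOB1.19 exosome library, and the lone exosome library left there was assumed to vary like the other groups.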

Other observations

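The values in this part come from gene lists fixed in advance, and no tests here were chosen only after the result was seen. In hFOB1.19 some cartilage genes were higher in both treated libraries than in the untreated one. The chondrocyte list of 5 genes had medians of 1.00 in the exosome and 1.25 in the supernatant library, each with 3 members higher and 1 lower, and -0.22 for exosome against supernatant. SOX9, a regulator of cartilage formation, went the other way at 7.28, 2.35 and 1.76 CPM in untreated, supernatant and exosome cells. The muscle list had 0.80 and 0.95, with 1 and 2 of 6 members past the rule, and CNN1 was at 54.3, 45.5 and 54.0 CPM. The small heat shock gene CRYAB was at 43.9, 177 and 104 CPM.

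Few reads were counted for bone marker genes in ROS1728. Sp7, Bglap and Ibsp had 0 reads in all 3 libraries, Runx2 had 0, 7 and 2 and Alpl 0, 1 and 0. A count of 0 may be a gap of the table, in which 6 of 13 mitochondrially encoded and 5 of 23 oxidative phosphorylation genes also had no read, so these values leave open how far the line keeps an osteoblast character, which was not tested. Of 24 osteoblast differentiation genes 8 had no read in any library. COL1A1 was at 1256 CPM in untreated hFOB1.19 cells and Col1a1 at 2.05 CPM in untreated ROS1728 cells.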
